A study of Mus musculus with 21 samples.

How the data were processed

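Total RNA of rostral cerebral cortex from mouse embryos at embryonic day 14 was hybridized to 21 Affymetrix arrays, 1 array per sample. Per the labels, RNA was extracted with the RNeasy Micro kit, amplified with MessageAmp Premier and labelled with biotin. The deposited values are log2 RMA expression values per probe set, as the authors' processing notes name RMA. The version and settings of RMA and the genome build behind the probe sets are not given in the sources used here. The columns of a line share nearly 1 distribution and those of the 3 lines differ, so that the arrays appear to have been normalized per line. No value was missing, and all 21 columns were used.

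Of 45101 probe sets, 64 were controls, 9160 named no gene, 932 named several genes and 34945 named 1 gene. Of the last, 34741 had their symbol in the RefSeq gene table of mouse assembly GRCm38.p6, which served for chromosome names and the order of neighbouring genes. Probe sets were kept where at least 3 arrays lay above the 40th percentile of all non-control probe sets of that array, which left 29474, of which 25140 named 1 gene. Each gene was represented by its kept probe set with the highest mean over all arrays, giving 13850 genes, 7329 of them with 1 kept probe set. Probe sets without a single gene were not used for gene results, and some genes are unnamed here for that reason.

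Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, eBayes), in 1 linear model of the 6 groups over all arrays, with 15 residual and 3.54 prior degrees of freedom. Contrasts took each mutant minus the littermate controls of its line, the differences between these changes for each pair of lines, and the differences between control groups. The p-values were adjusted by Benjamini-Hochberg per contrast, and a gene was called at an adjusted p under 0.05. Where every array of a group was at or below the 40th percentile that the filter uses, between 5.37 and 5.6 over the arrays, the fold is given as at least the mean of the other group over the level of each array. This bound was chosen after the data were seen. All tests were two-sided. An error given after a log2 change or a difference is the standard error of the fit. The groups, tests, gene lists, rule for named genes and most other settings were fixed before the data were examined. The labels state no test.

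The genes named for each mutant were Pax6, the 10 largest rises and 10 largest falls among called genes whose mutant arrays all lay beyond all control arrays, and up to 4 members with the smallest p of each list. A set of index genes of cortical development was added. For each difference between mutants the 5 largest in each direction were named, for shared changes up to 10 per direction, near Pax6 up to 5 per line and for controls the 3 largest per direction. Fewer are printed where the text would become a list, and genes chosen otherwise are said to be.

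Written from general knowledge, 25 gene lists held 449 symbols, 388 of them tested, for cell types, pathways and phases of the cell cycle, with markers of other cell types that the dissected tissue could hold. Some genes stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists per contrast, and again with an estimated correlation and with fry. The lists were tested in the 3 mutant comparisons and in the Leca4 and Leca2 difference, and with an estimated correlation no list was called in these 4. Counts adjusted over the list alone take the same p-values and adjust them within the list. Shared changes were set against the number that independent lists of the same sizes would share. Calls near Pax6 were compared with calls elsewhere by Fisher's exact test. Control probe sets for the 3' and 5' ends of Gapdh and Actb were compared by exact permutation tests.

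The other settings tried were a fit of only the groups compared, a block of replicate numbers, no filter and a stricter one at the 60th percentile, every probe set on its own, the mean of a gene's probe sets, a trend and robust variance, array weights, quantile normalization across all arrays, centring on the median, an adjusted p under 0.10, a change of at least 1.4-fold, all 129 S6 controls together, windows of 50 and 200 genes around Pax6 and leaving out each array in turn. Added after the data were seen were a term for sex, the removal of genes near Pax6 and on the sex chromosomes, and list tests on quantile normalized and centred values. The pipeline was tested on simulated data with 200 changed genes per mutant among 13850. It was run on a single random draw per mutant, which does not rank the lines. Of 67 genes changed by log2 0.5 it recovered 51 (76.1%) for Sey and for Leca4 and 56 (83.6%) for Leca2. Of genes changed by log2 1 it recovered between 98.5% and 100%. Of the genes it called 7.11%, 3.17% and 6% were unchanged ones. The simulated noise was normal and independent between genes, with the same spread in all groups and no uneven sex. These shares therefore need not hold for the real arrays, where genes are correlated. Figures were drawn in Python 3.11.15.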

Results

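Gene expression was measured on 21 Affymetrix arrays hybridized with total RNA from rostral cerebral cortex of mouse embryos at embryonic day 14. The arrays fell into 6 groups, the mutants and the control littermates of 3 lines that carry different mutations of Pax6. Pax6 encodes a transcription factor with a paired domain and a homeodomain that radial glia of the dorsal telencephalon express. The Small-eye (Sey) allele truncates the protein. The labels place the study on subdomains of the paired domain and do not say where the Leca4 and Leca2 mutations lie. From general knowledge of the alleles, not checked here, these are the PAI and the RED subdomain. Sey was represented by 4 mutant and 3 control arrays, Leca4 by 3 mutant and 4 control arrays and Leca2 by 4 mutant and 3 control arrays. Sey embryos were of a C57BL/6J and DBA/2J hybrid background, and both Leca lines were of a 129 S6 background. The labels describe the arrays of a group as biological replicates, so the p-values measure the spread between samples, and the number of arrays limits the precision.

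Array medians lay between 6.03 and 6.07 on the log2 scale in the Sey line, between 6.25 and 6.26 in Leca4 and between 6.12 and 6.18 in Leca2, and each mutant was compared with the controls of its own line. Arrays of the same group correlated with r between 0.9899 and 0.9968 across probe sets. The sex of each embryo was read from Xist, the transcript that silences an X chromosome in females, and from the Y-linked genes Eif2s3y and Kdm5d. The Sey mutants were 1 male and 3 females against 3 male controls. The Leca4 mutants were 2 males and 1 female against 3 males and 1 female, and the Leca2 mutants 2 males and 2 females against 3 female controls. The log2 difference between 3' and 5' control probe sets of Gapdh, a sign of RNA quality, was 0.00 between Sey mutants and controls and 0.06 in Leca4 and in Leca2. The exact permutation p of these differences was 1, 0.0857 and 0.0571, and the smallest the design allows is 0.0286. For Actb the differences were -0.02, 0.06 and 0.03 in Sey, Leca4 and Leca2 (exact p = 0.4, 0.0857 and 0.343). A gene is said to rise, fall or change where its adjusted p in limma was under 0.05.

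Pax6 transcript itself was higher in all 3 mutants than in their littermates. The probe set with the highest mean rose 1.47-fold in Sey, from 10.60 ± 0.04 (SD, n = 3) to 11.16 ± 0.17 (SD, n = 4) on the log2 scale (adjusted p = 0.000184 in limma). In Leca4 it rose 1.4-fold, from 11.54 ± 0.11 (SD, n = 4) to 12.03 ± 0.17 (SD, n = 3; adjusted p = 0.00276 in limma). In Leca2 it rose 1.9-fold, from 11.22 ± 0.10 (SD, n = 3) to 12.14 ± 0.10 (SD, n = 4; adjusted p = 1.1e-05 in limma). Each mutant array lay above every control array of its line. The other probe sets of Pax6 gave smaller changes in Leca4, of 0.07, 0.17 and 0.16, with adjusted p of 0.671, 0.65 and 0.36. With the mean of all its probe sets, Pax6 in Leca4 changed by 0.22 and was no longer called (adjusted p = 0.0893). In Sey the same probe sets changed by 0.19, 0.60 and 0.57 (adjusted p = 0.0874, 0.00901 and 9.25e-05), and in Leca2 by 0.42, 0.86 and 0.34 (adjusted p = 0.00703, 0.00943 and 0.12).

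**Figure D1:**
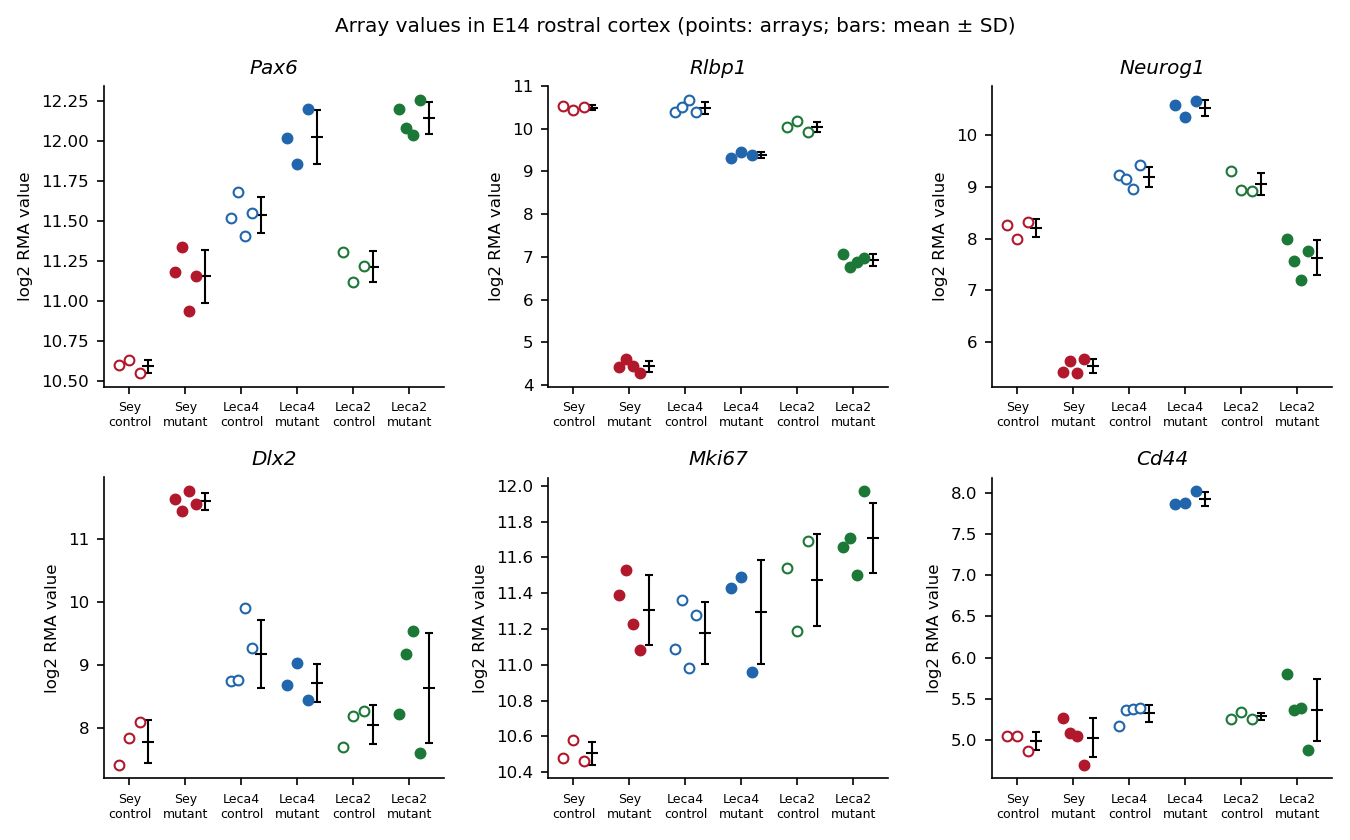
Log2 RMA values of 6 genes in each of the 21 arrays (vertical axis, its range set per gene), by line, with open points for controls, filled points for mutants and bars for the mean ± SD. Rlbp1 was lower in every mutant array than in every control array of its line, Neurog1 was lower in Sey and Leca2 and higher in Leca4, and Dlx2 and Mki67 were higher in every Sey mutant array than in the Sey controls.

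The Sey comparison asks what loss of full-length Pax6 does to the transcripts of the embryonic cortex. In Sey mutants the proneural genes Neurog1 and Neurog2 fell, the homeobox genes Dlx1, Dlx2 and Dlx5 rose, and so did all measured genes of the fixed lists of DNA replication and mitosis. Rlbp1, which encodes a retinaldehyde-binding protein, was at least 34.5-fold lower in the mutants, where every array was at or below the level of the filter (4.44 ± 0.13, SD, n = 4), than in the controls (10.50 ± 0.06, SD, n = 3; adjusted p = 9.63e-20 in limma). Dlx2, a homeobox gene of interneuron precursors, was 14.1-fold higher (11.60 ± 0.13 against 7.78 ± 0.34, SD, n = 4 and 3; adjusted p = 2.42e-07 in limma). Neurog2, a proneural gene of the dorsal cortex, was 3.06-fold lower (10.71 ± 0.22 against 12.32 ± 0.03, SD; adjusted p = 1.52e-08). Of 13850 genes, 2791 changed in Sey, 1488 upward and 1303 downward, and 223 of them changed by more than 2-fold.

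Among the largest rises of genes whose mutant arrays all lay beyond all control arrays were those of the Dlx family and of Dlx6os1, a transcript antisense to Dlx6. The log2 change (± SE) was 4.55 ± 0.41 for Dlx6os1, 3.88 ± 0.42 for Dlx1, 3.76 ± 0.27 for Dlx5 and 2.96 ± 0.18 for Dlx6. Slc18a2, the vesicular monoamine transporter, rose by 3.64 ± 0.39, Asb4 by 3.61 ± 0.23, the homeobox genes Gsx2 and Uncx by 3.15 ± 0.28 and 2.99 ± 0.30, and Wls, which is needed for Wnt secretion, by 2.99 ± 0.15. Beside Rlbp1, the largest falls included those of the transcription factor gene Dmrta1, with a log2 change of -3.66 ± 0.28, and of the uncharacterized 9130024F11Rik (-2.72 ± 0.25). The proneural genes Neurog1 and Neurod4 changed by -2.67 ± 0.15 and -2.62 ± 0.13, and the chemokine gene Cxcl12 by -2.55 ± 0.18. Lratd1 (-2.61 ± 0.18), Jph1 (-2.51 ± 0.11), the transcription factor gene Tfap2d (-2.44 ± 0.37) and Kif26b (-2.37 ± 0.12) also fell. Some of these changes are not measured sizes and have no order among the largest, because every array of 1 group was at or below the level of the filter, between 5.37 and 5.6. With that group set to the level, the rise was at least 6.49-fold for Dlx6, 5.78-fold for Slc18a2 and 3.47-fold for Uncx, and the fall at least 4.56-fold for Dmrta1, 4.38-fold for Neurod4, 3.54-fold for Jph1 and 1.95-fold for Tfap2d. The same holds for the rises of Gbx2, Eya2 and Paupar given below (at least 2.34, 2.12 and 2.18-fold). The level is not a sharp limit, since Xist in males, where it is not expected, read up to 6.55. Genes with 1 group of arrays close to the level, among them Neurog1, Asb4, Wls, Gsx2 and Olig2 in Sey, Fbln7, Dbx1, Dmrta1 and Meis1 in Leca4 and Gna14 in Leca2, therefore have sizes and ranks that background can set in part, also in the differences between lines. Other kept probe sets changed less and were not called for Jph1 (-0.12, adjusted p = 0.384), Cux2 (-0.09 for 1 of 2 others, adjusted p = 0.53) and Lmo7 (-0.18, adjusted p = 0.312). These are examples. Among the kept probe sets, the smallest change in Sey was -0.05 for Slc1a3 (of 5), -0.1 for Neurod2 (of 3), 0.2 for Prrx1 (of 5) and -0.25 for Neurog1 (of 2).

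All 26 measured genes of the G1/S and DNA replication list rose in Sey, as did all 27 of the G2/M and mitosis list, and the counts were the same when adjusted over the list alone. The median log2 change was 0.64 and 0.69. Among the replication genes, the licensing factors Cdc6 and Cdt1 rose by 1.18 ± 0.12 and 1.03 ± 0.11 and the helicase subunit gene Mcm6 by 0.83 ± 0.07. Among the mitotic genes, Top2a, a DNA topoisomerase, rose by 0.91 ± 0.08, the kinetochore motor gene Cenpe by 0.83 ± 0.10 and the proliferation marker Mki67 by 0.80 ± 0.14. Both lists shifted upward by camera (adjusted p = 2.91e-23 and 3.23e-23), and neither was called with an estimated correlation (adjusted p = 0.088 with an estimated correlation for both). Of 19 regulators of G1, 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00915; adjusted p = 0.246 with an estimated correlation). Cyclin D2 (Ccnd2) rose by 0.68 ± 0.06, the cyclin-dependent kinase inhibitor gene Cdkn1c by 0.77 ± 0.11 and Rbl1 of the retinoblastoma family by 0.64 ± 0.09, while the chromatin gene Hmga2 had a log2 change of -1.68 ± 0.19. Cyclin D1 (Ccnd1) was not called, at 0.06 ± 0.12 (adjusted p = 0.812).

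Of 21 measured genes of the ventral telencephalon and GABAergic neurons, 13 rose and 1 fell in Sey (14 and 2 adjusted over the list alone), with a median log2 change of 1.42. Olig2, a regulator of ventral progenitors, rose by 2.73 ± 0.21. The list shifted upward (camera adjusted p = 7.58e-08; adjusted p = 0.0956 with an estimated correlation). Of 24 cortical projection neuron genes, 16 fell and 2 rose, also when adjusted over the list alone, with a median of -0.59 (camera adjusted p = 7.58e-08; adjusted p = 0.088 with an estimated correlation). Examples are the upper-layer gene Cux2 (-1.31 ± 0.15), the neuropilin gene Nrp1 (-1.47 ± 0.13), the vesicular glutamate transporter gene Slc17a6 (-1.18 ± 0.09), Neurod2 (-0.77 ± 0.08) and the T-box gene Tbr1 (-0.86 ± 0.16). Of 22 genes of neurogenic intermediate progenitors, 12 fell and 4 rose (12 and 6 adjusted over the list alone; median -0.28; camera adjusted p = 3.68e-04; adjusted p = 0.207 with an estimated correlation). The T-box gene Eomes changed by -1.64 ± 0.10 and the somatostatin receptor gene Sstr2 by -0.98 ± 0.07, whereas Dll3, a Notch ligand gene, rose by 0.86 ± 0.11. Of 20 pan-neuronal genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.24), among them Syt4 (-0.86 ± 0.14), Rbfox3 (-0.62 ± 0.10) and Snap25 (-0.61 ± 0.10). The pan-neuronal shift (camera adjusted p = 0.00915; adjusted p = 0.538 with an estimated correlation) was not called once a term for the sex of the embryo was in the model (adjusted p = 0.0667).

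Genes of cell adhesion and axon guidance mostly fell in Sey, 21 of 35 against 6 that rose (22 and 7 adjusted over the list alone; median -0.36; camera adjusted p = 4.55e-07; adjusted p = 0.0971 with an estimated correlation). The netrin receptor gene Unc5d changed by -2.34 ± 0.16, the cadherin gene Cdh8 by -1.56 ± 0.12 and the ephrin receptor gene Epha3 by -0.95 ± 0.06. Of 9 genes of the antihem and lateral pallium, 5 fell and 1 rose, also when adjusted over the list alone (median -0.42; camera adjusted p = 0.0234; adjusted p = 0.088 with an estimated correlation). Cdh4 changed by -1.75 ± 0.17, Nrg3 by -1.08 ± 0.16 and the Wnt antagonist gene Sfrp2 by -0.42 ± 0.11, and the ephrin gene Efna5 rose by 0.64 ± 0.13. This list was not called without Sey mutant replicate 1 or without Sey control replicate 2 (highest adjusted p = 0.0665), and Sfrp2 was not called without Sey control replicate 2 (adjusted p = 0.0595) or where a change of at least 1.4-fold was required. Of 12 genes of Cajal-Retzius cells, the early-born neurons of the marginal zone, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.64; camera adjusted p = 8.1e-05; adjusted p = 0.088 with an estimated correlation). Calb2, Lhx5 and Ebf3 rose by 1.21 ± 0.19, 1.15 ± 0.13 and 0.87 ± 0.10. Of 22 genes reported elsewhere as targets of Pax6, 8 fell and 3 rose, also when adjusted over the list alone (median -0.09, mean -0.54; camera adjusted p = 0.00691; adjusted p = 0.0956 with an estimated correlation). The corepressor gene Tle1 and the progenitor gene Sox2 of that list rose by 1.04 ± 0.09 and 0.55 ± 0.13.

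The other lists were not called as shifted in Sey by camera with all arrays and the filter. With fry, which does not compare a list with other genes, the diencephalic, olfactory and meninges lists were called (adjusted p = 5.63e-06, 6.81e-05 and 0.011). Of 26 radial glia genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone), with Notch1 up by 0.54 ± 0.13 and the glutamate transporter gene Slc1a3 and the aldolase gene Aldoc at -1.44 ± 0.10 and -1.66 ± 0.11. The list of cortical hem and Wnt genes held 4 that rose and 4 that fell among 16 (5 and 4 adjusted over the list alone), with Wnt5a up by 1.21 ± 0.19 and Rspo3 at -0.92 ± 0.09. Among 20 genes of Notch signalling 4 rose and 3 fell, also when adjusted over the list alone, with the ligand gene Jag1 at -0.52 ± 0.07. Of 8 olfactory genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Sp8 up by 2.88 ± 0.24 and Eya2 by 1.72 ± 0.16. The camera adjusted p of the olfactory list was 0.0543, and it was 0.042 with the arrays quantile normalized again or centred on their median and 0.0451 without the filter. That list was also called without Sey mutant replicate 2 or 3 or Sey control replicate 2 (lowest adjusted p = 0.0371). Of 7 diencephalic genes 3 rose and 1 fell, also when adjusted over the list alone, with Gbx2 up by 2.33 ± 0.08 and Lhx9 by 1.73 ± 0.28, and the list was called without the filter (camera adjusted p = 0.0304). The list of Fgf signalling and rostral patterning had 2 up and 2 down of 15 (2 and 4 adjusted over the list alone), with Etv5 at -0.70 ± 0.08, and that of hypoxia and glycolysis 1 up and 2 down of 16, also when adjusted over the list alone, with Ndrg1 at -1.16 ± 0.19. Of 11 genes of meninges and mesenchyme 2 rose and 1 fell (2 and 2 adjusted over the list alone), and those that rose were Crabp2 (1.78 ± 0.24) and Prrx1 (1.46 ± 0.17). The p53 and apoptosis list had 1 up and 3 down of 12 (3 and 3 adjusted over the list alone). The endothelial list had 1 up of 18 and the choroid plexus list 1 down of 7, and both had 0 when adjusted over the list alone. None of 12 microglial, 8 erythroid and 4 sex-linked genes was called, also when adjusted over the list alone. The sex-linked genes still had large changes, with a median of -2.91. Xist changed by 4.09, Eif2s3y by -3.64, Kdm5d by -4.34 and Uty by -2.18, where 1 of 4 mutants and all 3 controls were male. Median, mean and test differed in sign for the erythroid, Fgf, meninges, p53 and radial glia lists.

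Sex was uneven in this line, and with a term for it in the limma model, chosen after the data were seen, 1936 genes were called in Sey, 1872 of them among the 2791. Requiring a change of at least 1.4-fold left 1057 genes.

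**Figure D2:**
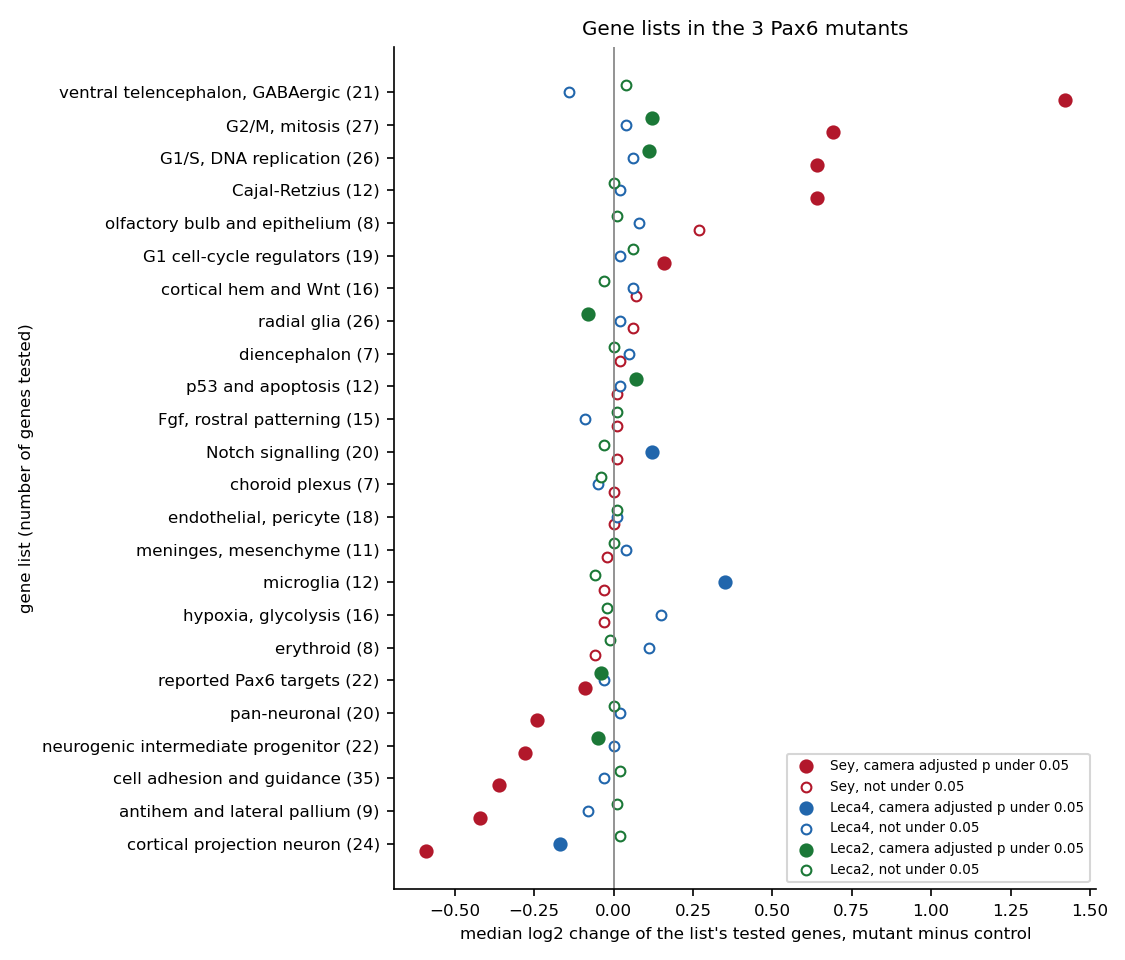
Median log2 change of the tested genes of 24 gene lists (horizontal axis) in Sey (red), Leca4 (blue) and Leca2 (green), with the number of genes tested in brackets and filled points where camera's adjusted p was under 0.05; the sex-linked list is not drawn. The Sey medians run from -0.59 for cortical projection neurons to 1.42 for the ventral telencephalon, and all those of Leca4 and Leca2 lie between -0.17 and 0.35.

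The Leca4 comparison asks what that mutation does. In Leca4 mutants 779 genes changed, 469 upward and 310 downward, and 80 by more than 2-fold. Cd44, the hyaluronan receptor, was at least 5.04-fold higher in the mutants (7.92 ± 0.09, SD, n = 3) than in the controls (5.33 ± 0.10, SD, n = 4, every array at or below the level of the filter; adjusted p = 1.65e-09 in limma). Neurog1 was 2.53-fold higher (10.54 ± 0.16 against 9.20 ± 0.19, SD; adjusted p = 1.56e-05), with a change of 0.70 by the mean of its probe sets, and Rlbp1 was 2.17-fold lower (9.38 ± 0.07 against 10.49 ± 0.14, SD; adjusted p = 9.99e-08). The urea transporter gene Slc14a1 was at least 2.4-fold lower (every mutant array at or below the level; adjusted p = 1.71e-09). The second kept probe set of Neurog1, at a mean of 5.4 over all arrays and so near the level of the filter, changed by 0.07 in Leca4, -0.25 in Sey and -0.14 in Leca2 (adjusted p = 0.824, 0.151 and 0.911). None of the listed genes of DNA replication and mitosis changed.

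Among the largest rises were those of Cryab, a small heat shock protein gene, with a log2 change (± SE) of 3.09 ± 0.19, the retinoic acid-binding protein gene Crabp1 (2.66 ± 0.26) and the fibulin gene Fbln7 (2.66 ± 0.32). Dbx1, a homeobox gene of the antihem, rose by 2.52 ± 0.29, and the transcription cofactor gene Eya4 by 2.34 ± 0.19. The neuropeptide gene Adcyap1 was 5.27-fold higher (adjusted p = 2.08e-12). Also among the largest rises were Ccn2 at 2.43 ± 0.12, the collagen gene Col6a3 at 2.39 ± 0.18 and the nephronectin gene Npnt at 2.09 ± 0.09. Beside Slc14a1, the largest falls included those of Veph1 (-2.42 ± 0.28), Dmrta1 (-2.14 ± 0.28), the homeobox gene Meis1 (-2.05 ± 0.20) and the pentraxin gene Ptx3 (-1.91 ± 0.18). Aldh1l1, a folate enzyme gene of astroglia, changed by -1.75 ± 0.34 and the netrin gene Ntn4 by -1.38 ± 0.11. Cryab was at or below the level in all controls and Veph1 in all mutants, so that their changes have a bound alone, at least 5.03-fold and 2.54-fold. These genes, Cd44 and Slc14a1 therefore have no order among the largest changes. Of the 4 kept probe sets of Npnt, the 1 used changed most, and the lowest change was -0.08.

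Several markers that changed in Sey were not called in Leca4. The log2 change was -0.04 ± 0.12 for Neurog2 (adjusted p = 0.915), -0.12 ± 0.10 for Eomes (adjusted p = 0.569), 0.03 ± 0.16 for Tbr1 (adjusted p = 0.957), -0.45 ± 0.35 for Dlx2 (adjusted p = 0.563) and 0.12 ± 0.14 for Mki67 (adjusted p = 0.744). Neither the 26 genes of G1/S and DNA replication nor the 27 of G2/M and mitosis held a call by limma, also when adjusted over the list alone, and the lists had camera adjusted p of 0.447 and 0.731. Without Leca4 mutant replicate 2 the G1/S list was called (adjusted p = 0.0191). In all, 2531 genes had an unadjusted p under 0.05 in this comparison.

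Microglial genes shifted upward in Leca4, where 5 of 12 rose (7 adjusted over the list alone; median 0.35; camera adjusted p = 5.8e-05; adjusted p = 0.554 with an estimated correlation). The complement gene C1qa rose by 0.52 ± 0.10. Of the other calls, that of Lyz2 was lost in 4 of 7 fits with 1 array fewer, Csf1r in 3 and C1qc in 1. Their highest adjusted p by limma was 0.123, 0.087 and 0.055. Of 20 genes of Notch signalling 3 rose (4 adjusted over the list alone; median 0.12; camera adjusted p = 0.00431; adjusted p = 0.554 with an estimated correlation). The ligand gene Jag1 rose by 0.89 ± 0.07, and the list was not called without Leca4 control replicate 3 (adjusted p = 0.0524). Of 24 cortical projection neuron genes 5 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.17; camera adjusted p = 0.0301; adjusted p = 0.941 with an estimated correlation). Foxp2 changed by -0.60 ± 0.13, while Zfpm2 and Lmo4 rose by 0.63 ± 0.09 and 0.50 ± 0.08. This call was lost without Leca4 mutant replicate 1 or 3 or Leca4 control replicate 1 or 3 (highest adjusted p = 0.237) and with the mean of each gene's probe sets (adjusted p = 0.188).

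The remaining lists were not called as shifted in Leca4 by camera with all arrays. The cortical projection neuron list was not called with fry (adjusted p = 0.337). Of 26 radial glia genes 1 rose, Hopx (1.66 ± 0.14), and 4 fell (2 and 5 adjusted over the list alone), among them the tenascin gene Tnc (-1.33 ± 0.23). Of 22 reported Pax6 targets 5 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.145), and of 35 adhesion and guidance genes 6 fell and 2 rose (8 and 4 adjusted over the list alone; camera adjusted p = 0.171), among them Cdh8 (-1.20 ± 0.12) and Epha7 (-0.54 ± 0.09). The adhesion list was called without Leca4 mutant replicate 2 (adjusted p = 0.0136). Of 11 genes of meninges and mesenchyme 2 rose, Crabp2 (1.17 ± 0.24) and Prrx1 (0.95 ± 0.17), and 0 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.825). Wnt5a of the hem and Wnt list rose by 0.93 ± 0.19, Cdkn1c of the G1 regulators by 0.78 ± 0.11, Eya2 of the olfactory list by 1.17 ± 0.16 (all controls at or below the level, at least 1.55-fold) and Foxp1 of the ventral list by 0.70 ± 0.10. Median, mean and test differed in sign for the antihem, hem and Wnt, endothelial, pan-neuronal and radial glia lists. Without Leca4 mutant replicate 1 the number of genes called was 512. It was 400 in a fit of only the 7 arrays of the line, 450 with a block of replicate numbers and 330 where a change of at least 1.4-fold was required.

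The Leca2 comparison asks the same of the other allele. Here 66 genes changed, 24 upward and 42 downward, and 15 by more than 2-fold. Rlbp1 was 8.7-fold lower in the mutants (6.92 ± 0.13, SD, n = 4) than in the controls (10.05 ± 0.12, SD, n = 3; adjusted p = 1.9e-14 in limma). Neurog1 was 2.7-fold lower (7.63 ± 0.34 against 9.06 ± 0.21, SD; adjusted p = 3.55e-05). Slc14a1 changed by -1.95 ± 0.18 (log2 change ± SE), the G protein subunit gene Gna14 by -1.94 ± 0.17, Neurod4 by -1.49 ± 0.13, Cxcl12 by -1.44 ± 0.18, Lmo7 by -1.41 ± 0.20 and the insulin-like growth factor binding protein gene Igfbp5 by -1.28 ± 0.16. Emid1 and Dapp1 changed by -1.05 ± 0.14 and -1.01 ± 0.15, and Dapp1 was not called with a block of replicate numbers (adjusted p = 0.133). Among the largest rises were those of Asb4 (1.85 ± 0.23), Paupar, a noncoding transcript from upstream of Pax6 (1.48 ± 0.18), the glutamate transporter gene Slc1a2 (1.45 ± 0.22) and Tmem163 (0.96 ± 0.09). The other 2 kept probe sets of Slc1a2 changed by -0.05 and 0.17 (adjusted p = 0.984 and 0.892), and the other one of Igfbp5 by -0.27 (adjusted p = 0.816). Ddit4l rose by 0.79 ± 0.10. Slc14a1 was at or below the level of the filter in all mutants and Paupar in all controls, and the bound on the change was 1.23-fold for Paupar and none for Slc14a1.

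Several regulators that changed in Sey were not called in Leca2. The log2 change was -0.48 ± 0.12 for Neurog2 (adjusted p = 0.102), 0.04 ± 0.10 for Eomes (adjusted p = 1), -0.01 ± 0.16 for Tbr1 (adjusted p = 1), 0.59 ± 0.35 for Dlx2 (adjusted p = 0.872), 0.68 ± 0.28 for Gsx2 (adjusted p = 0.628, every control array at or below the level of the filter) and 0.24 ± 0.14 for Mki67 (adjusted p = 0.877). Neurog2 was called with array weights (adjusted p = 0.0495), and it and Mki67 were called against all 129 S6 controls (adjusted p = 0.009 and 0.0154), which brings in the separate normalization of the lines. The lists of G1/S and of G2/M genes shifted upward by medians of 0.11 and 0.12 (camera adjusted p = 4.6e-05 and 1.79e-04; adjusted p = 0.747 with an estimated correlation for both). No single member of either list was called by limma, also when adjusted over the list alone, while 948 of all genes had an unadjusted p under 0.05. Without Leca2 control replicate 2 neither list was called (adjusted p = 0.0603 and 0.427).

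Of 26 radial glia genes 2 fell and 1 rose in Leca2 (4 and 1 adjusted over the list alone; median -0.08; camera adjusted p = 7.93e-04; adjusted p = 0.676 with an estimated correlation), among them Aldoc (-0.64 ± 0.11; not called with the block of replicate numbers, adjusted p = 0.113). Of 22 reported Pax6 targets 1 fell, Rlbp1 (2 adjusted over the list alone; median -0.04; camera adjusted p = 0.0109; adjusted p = 0.665 with an estimated correlation). Of 22 genes of neurogenic intermediate progenitors 2 fell, Neurog1 and Neurod4 (3 adjusted over the list alone; median -0.05; camera adjusted p = 0.0109; adjusted p = 0.695 with an estimated correlation). The radial glia, target and intermediate progenitor lists were not called without Leca2 mutant replicate 3 (adjusted p up to 0.0532, 0.0581 and 0.0808), nor was the target list without Leca2 control replicate 1. Of 12 genes of p53 and apoptosis 1 rose, Ddit4l, also when adjusted over the list alone (median 0.07; camera adjusted p = 0.0233; adjusted p = 0.676 with an estimated correlation). That list was not called without Leca2 mutant replicate 1 or 3 or Leca2 control replicate 3 (highest adjusted p = 0.0971), nor with the sex term (adjusted p = 0.204), the mean of probe sets (adjusted p = 0.335) or no filter (adjusted p = 0.0785). The other 19 lists were not called with all arrays in the model of groups alone. The cortical projection neuron and pan-neuronal lists were called without Leca2 control replicate 1 (adjusted p = 0.0277 and 0.0433), and the ventral telencephalon list with a block of replicate numbers (adjusted p = 0.0298). With fry the target list kept its call, and the other 5 did not (adjusted p from 0.276 to 0.616). Median, mean and test differed in sign for the antihem, adhesion, choroid plexus, hem and Wnt, cortical projection neuron, diencephalon, erythroid, Fgf and hypoxia lists. Without Leca2 mutant replicate 2 the number of genes called was 40. With a block of replicate numbers it was 28 and with array weights 121. In a fit of only the 7 arrays of the line it was 27, and Lmo7 and Slc1a2 were no longer called (adjusted p = 0.154 and 0.0546).

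The changes in the mutants were compared directly, as the difference between the mutant-minus-control changes of each pair of lines. Between Leca4 and Leca2, lines of the same strain, 329 genes differed, 196 with the higher change in Leca4 and 133 with the higher change in Leca2. The change of Neurog1 was 2.77 ± 0.22 (log2 ± SE) higher in Leca4 than in Leca2 (adjusted p = 2.99e-07 in limma). Differences in the same direction were 2.90 ± 0.27 for Cryab, 2.74 ± 0.37 for Crabp1, 2.69 ± 0.27 for Eya4 and 2.59 ± 0.41 for Dbx1. The change was lower in Leca4 for Dmrta1 (-2.70 ± 0.39), Meis1 (-2.15 ± 0.28), the uncharacterized G630016G05Rik (-2.06 ± 0.34), Tnc (-1.73 ± 0.33) and Ptx3 (-1.70 ± 0.26). Microglial genes changed more in Leca4, with a median difference of 0.43 (camera adjusted p = 1.39e-04; adjusted p = 0.725 with an estimated correlation), though 0 of 12 differed singly by limma and 7 did when adjusted over the list alone. Genes of Notch signalling differed by a median of 0.20 (2 of 20 called, also when adjusted over the list alone; camera adjusted p = 0.0061; adjusted p = 0.935 with an estimated correlation). The lists of G1/S and G2/M genes were not shown to differ between these mutants (camera adjusted p = 0.307 and 0.199). Both were called without Leca2 mutant replicate 3 or Leca2 control replicate 1, and the G2/M list also without Leca4 control replicate 3 (lowest adjusted p = 0.00915 and 0.00194). The intermediate progenitor list (camera adjusted p = 0.0953) was called without Leca2 mutant replicate 1 or 4, Leca4 mutant replicate 2 or Leca4 control replicate 2 (lowest adjusted p = 0.00303). The radial glia list was called without Leca2 mutant replicate 4, Leca2 control replicate 2 or Leca4 mutant replicate 2, the cortical projection neuron list without the latter 2 (lowest adjusted p = 0.0167 for both), and the ventral telencephalon list without Leca2 mutant replicate 4 (adjusted p = 0.0425). With a block of replicate numbers the cortical projection neuron, radial glia and ventral telencephalon lists were called (adjusted p = 0.0264, 0.026 and 0.0264), and with fry the microglial and Notch lists were not (adjusted p = 0.0743 and 0.128). Median, mean and test of the difference varied in sign for the antihem, hem and Wnt, and endothelial lists. Without Leca2 control replicate 1 the number of differing genes was 201. With the block it was 148, and 128 (38.9%) of the 329 were kept.

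Between Sey and Leca4 the change differed for 1778 genes, 936 of them with the higher change in Sey. The log2 difference was 5.35 ± 0.58 for Dlx6os1, 4.76 ± 0.60 for Dlx1, 4.43 ± 0.55 for Slc18a2, 4.27 ± 0.50 for Dlx2 and 4.05 ± 0.39 for Dlx5. In the other direction it was -4.94 ± 0.12 for Rlbp1, -4.01 ± 0.22 for Neurog1, -2.97 ± 0.46 for Fbln7, -2.84 ± 0.27 for Cryab and -2.60 ± 0.17 for Ccn2. Between Sey and Leca2 it differed for 927 genes, 475 of them higher in Sey. These included Dlx6os1 (4.16 ± 0.58), Uncx (3.69 ± 0.43), Dlx5 (3.50 ± 0.39), Dlx1 (3.47 ± 0.60) and Sp8 (3.27 ± 0.34), and in the other direction Dmrta1 (-4.22 ± 0.39), Rlbp1 (-2.93 ± 0.12), Lratd1 (-2.66 ± 0.25), 9130024F11Rik (-2.62 ± 0.35) and the glucagon gene Gcg (-2.50 ± 0.27). Strain differs between Sey and the Leca lines in both of these comparisons. Sex is uneven too, in opposite directions in Sey and Leca2. The Sey mutants had 1 male of 4 against 3 male controls, and the Leca2 mutants 2 of 4 against 3 female controls. The Sey and Leca2 difference is therefore confounded with sex in part. The differences of Rlbp1, Slc18a2, Uncx, Dmrta1, Fbln7 and Cryab, here and above, include a group with every array at or below the level of the filter, so the background sets their size and their SE in part. With the block the Sey and Leca4 difference had 1015 genes and the Sey and Leca2 difference 559. The latter had 293 genes with a sex term in the model, and 285 (30.7%) of the 927 were kept. It had 529 genes without Leca2 control replicate 1 and 582 without Sey control replicate 1.

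Changes shared between the mutants were counted from the comparisons with separate controls. Sey and Leca4 shared 189 genes changed in the same direction, 86 up and 103 down, where independent lists of these sizes would share 50.4 and 29.2, and 91 genes changed in opposite directions, where 77.4 would be shared. Sey and Leca2 shared 45 genes in the same direction, 12 up and 33 down (2.58 and 3.95 for independent lists), and 0 in opposite directions (6.77 for independent lists). Those 45 were 68.2% of the genes called in Leca2, and 57 of the 66 had the same sign in Sey. Leca4 and Leca2 shared 18 genes in the same direction, 4 up and 14 down (0.813 and 0.94 for independent lists), and 8 in opposite directions (1.96 for independent lists). Across all genes, which are not independent replicates, the changes correlated with Pearson r of 0.17 and Spearman rho of 0.09 between Sey and Leca4, 0.30 and 0.28 between Sey and Leca2, and -0.01 and -0.08 between Leca4 and Leca2. The 189 fell to 116 without Leca4 mutant replicate 1 and to 124 without Leca4 mutant replicate 3. In a fit of only the groups compared the 189, 45 and 18 became 113, 22 and 8, with the block 108, 24 and 7, and with array weights the 45 and 18 became 83 and 34.

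In all 3 mutants 2 genes rose and 11 fell. Beside Pax6 the gene that rose was Carhsp1, by 1.33 ± 0.07 in Sey, 0.42 ± 0.07 in Leca4 and 0.36 ± 0.07 in Leca2. Its call in Leca2 was lost in 6 of the 7 fits with 1 array fewer, all but the one without Leca2 mutant replicate 4, with a highest adjusted p of 0.166. It was also lost in a fit of only the 7 arrays of the line (adjusted p = 0.122), with the block (0.176), with the mean of probe sets (0.0786) and with the sex term (0.0664). Among those that fell, Rlbp1 had log2 changes of -6.05, -1.12 and -3.12 in Sey, Leca4 and Leca2. In the same order Slc14a1 changed by -2.30 ± 0.18, -3.09 ± 0.18 and -1.95 ± 0.18, Gna14 by -1.36 ± 0.17, -0.86 ± 0.17 and -1.94 ± 0.17 and Lmo7 by -1.70 ± 0.20, -1.08 ± 0.20 and -1.41 ± 0.20. The Sey mutants were at or below the level of the filter for Rlbp1, Slc14a1 and Gna14, and so were the mutants of all lines for Slc14a1. Calls of other shared genes also depended on single arrays. That of Igfbp5 in Leca4 was lost in 5 of 7 fits with 1 array fewer, Gpc3 in Sey in 4 and Prkcb in Leca2 in 3. Map7 in Leca2 and Aldoc in Leca4 lost theirs in 1 fit each. Pax6 in Leca4 was not called with the mean of its probe sets, as given above.

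**Figure D3:**
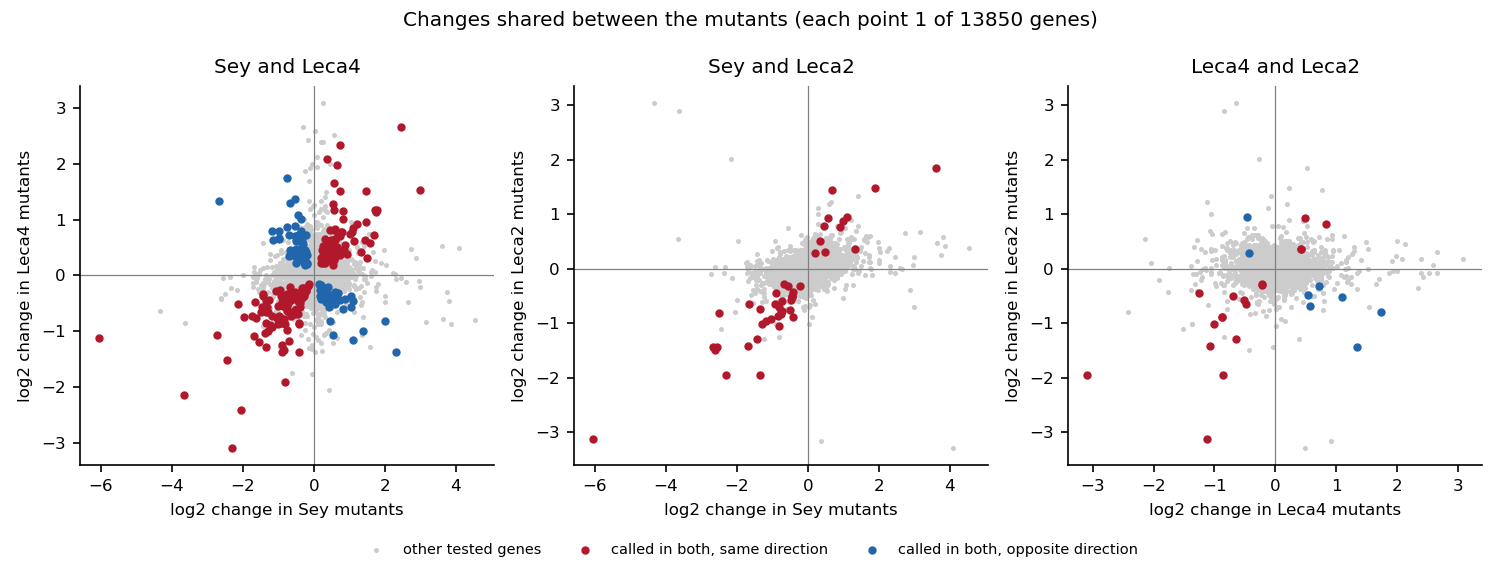
Log2 changes (mutant minus control) of 13850 genes in each pair of mutants, on both axes, with genes changed in both mutants in the same direction in red and in opposite directions in blue. Sey and Leca2 have 45 red and 0 blue points, Sey and Leca4 189 and 91, and Leca4 and Leca2 18 and 8.

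Genes linked to Pax6 on chromosome 2 were looked at separately, because a mutant allele carries the neighbouring chromosome with it. Of the 100 tested genes on each side of Pax6, 24 of 200 changed in Leca4 (12%, against 5.54% elsewhere; odds ratio 2.33, Fisher's exact test, two-sided, p = 4.84e-04). In Leca2 they numbered 6 of 200 (3%, against 0.428%; odds ratio 7.2, Fisher's exact p = 3.25e-04; with a block of replicate numbers odds ratio 5.47, p = 0.0581), and in Sey 45 of 200 (22.5%, against 20.2%; odds ratio 1.15, Fisher's exact p = 0.425). With 200 genes on each side the Sey share was 109 of 400 and passed the test (odds ratio 1.5, Fisher's exact p = 6.23e-04). In Leca4 the genes with the smallest p near Pax6 were Cd44, Rcn1, which encodes a calcium-binding protein (1.14 ± 0.13), the autophagy gene Ambra1 (0.90 ± 0.09), Mpped2 (0.50 ± 0.07) and Gm13889 (-1.15 ± 0.14, against 1.10 ± 0.14 in Sey). In Leca2 they included Paupar, Slc1a2, Immp1l (0.51 ± 0.08) and Aqr (0.37 ± 0.06). Aqr changed sign to -0.04 with the mean of its probe sets, and neither it nor Immp1l was called in a fit of only the 7 arrays of the line (adjusted p = 0.0718 and 0.146) or with the block (adjusted p = 0.113 and 0.133). The second probe set of Ambra1 changed by 0.12 in Leca4 (adjusted p = 0.817). In Sey they were Depdc7 (2.03 ± 0.14), Paupar (1.90 ± 0.18), Elp4, a gene next to Pax6 (0.89 ± 0.11), Arhgap11a (0.64 ± 0.07) and the secretogranin gene Scg5 (-0.76 ± 0.07).

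**Figure D4:**
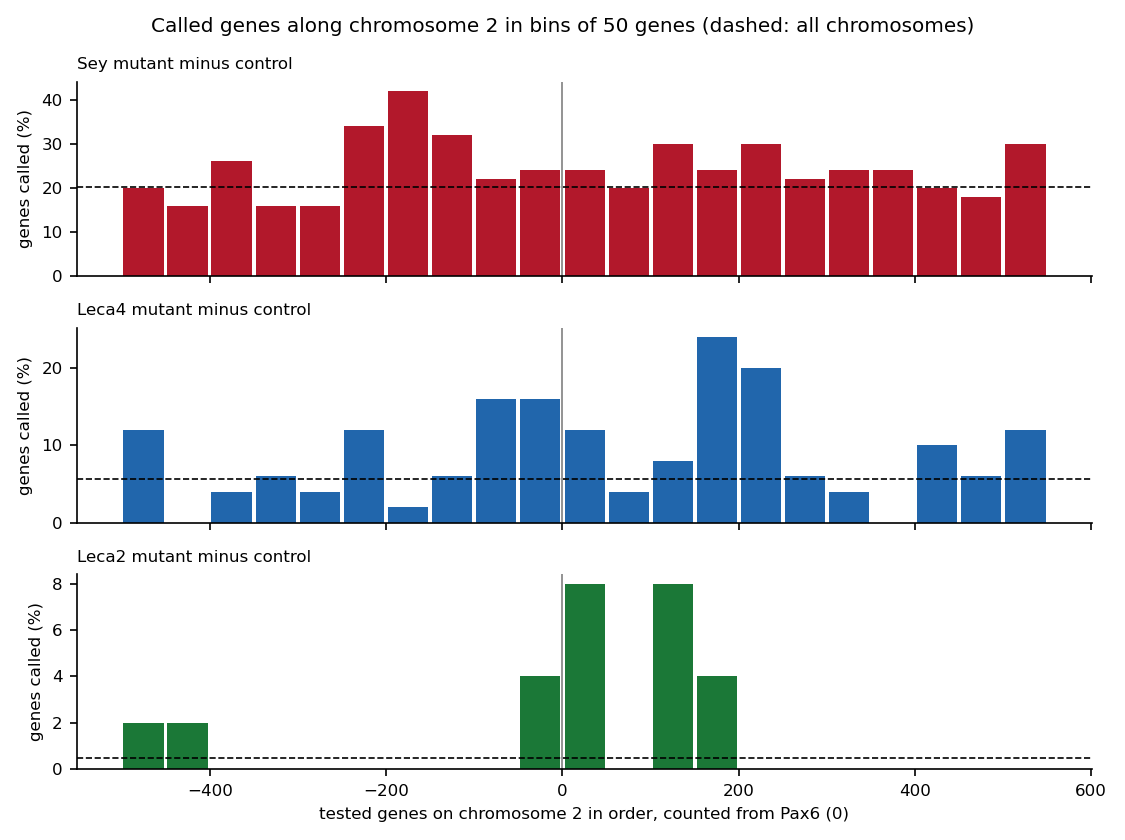
Share of genes called (vertical axis, percent, its range set per line) in consecutive bins of 50 tested genes along chromosome 2, by their order from Pax6 (horizontal axis, 0 at Pax6), in each mutant, with a dashed line at the share over all chromosomes. That share is 20.2% in Sey, 5.62% in Leca4 and 0.477% in Leca2, and the bins beside Pax6 lie above it in all 3 lines. Other bins are higher in Sey (42% at 151 to 200 genes before Pax6) and in Leca4 (24% and 20% at 151 to 250 genes after it), and in Leca2 the bin at 101 to 150 genes after it equals the highest (8%). The end bins, of 20 and 42 genes, are not drawn, and the first held 45% in Sey.

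The control groups were compared with each other as a background to the mutant comparisons, since they differ by line and in part by strain and sex. The arrays appear to have been normalized separately per line, which these control differences hold and the mutant comparisons do not. Between the controls of the Leca4 and Leca2 lines, of the same strain, 6561 genes differed, 5795 of them higher in Leca4, with a median over all genes of 0.16. With the arrays quantile normalized again 4120 genes differed, 2196 and 1924 by direction. Cldn34c1, a claudin-like gene on the X chromosome, was 5.23 ± 0.14 (log2 ± SE) higher in Leca4 controls, and Galc, a lysosomal galactosylceramidase gene, and Zfp133-ps had differences of -2.65 ± 0.73 and -1.84 ± 0.19. Between the controls of Sey and those of both Leca lines 10067 genes differed, 8887 of them lower in Sey, with a median over all genes of -0.30, and 7733 did with the arrays quantile normalized again. Cldn34c1 was higher in Sey controls by 3.06 ± 0.13, the photoreceptor gene Rpgrip1 by 2.56 ± 0.13 and the myosin gene Myo7a by 2.49 ± 0.15. The uncharacterized 2010315B03Rik had a difference of -2.78 ± 0.11, and Pdxdc1 one of -4.77 ± 0.89 that became 0.08 with the mean of its probe sets. Every array was at or below the level of the filter for Cldn34c1 in the Leca2 controls, Zfp133-ps in the Leca4 controls, Myo7a in both groups of Leca controls, and 2010315B03Rik and Pdxdc1 in the Sey controls, so that the size of these differences is set in part by background.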

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

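The tests in this part were chosen before their results were seen, except the model with a term for sex. Which of the genes covered by the naming rule appear in the text, and so entered the test for arrays far from the others, was decided after their values were seen. In the groups of 4 arrays, the gap between the highest or lowest array and its nearest neighbour was divided by the range of the group for each named gene and array measure. The ratio passed Dixon's critical value for groups of 4 in 24 of 429 such tests, where chance passes about 1 in 20, or 21.4. Those for Xist, Eif2s3y and Kdm5d follow the sex of the embryo. In the Sey mutants, replicate 2 had ratios of 0.961 for Eif2s3y, 0.972 for Kdm5d and 0.959 for Xist, and in the Leca4 controls replicate 2 had 0.938, 0.949 and 0.898.

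Among the other genes of the Sey mutants, replicate 3 was high for Galc (ratio 0.854), Myo7a (0.878) and Ntn4 (0.869). Replicate 4 was high for Pdxdc1 (0.944) and low for Lratd1 (0.898), and replicate 1 was low for Arhgap11a (0.884). In the Leca4 controls replicate 1 was low for Cd44 (0.855), Npnt (0.981) and Pdxdc1 (0.85, at 6.13 against a mean of 10.2 in the others). Replicate 2 was low for Igfbp5 (0.95), and replicate 3 was high for Slc18a2 (0.931) and low in its array median (0.857, at 6.25 against 6.26). In the Leca2 mutants replicate 1 was low for G630016G05Rik (0.889) and high for Tmem163 (0.961), and replicate 2 was low for Jag1 (0.845). Replicate 3 was high for Lmo7 (0.878) and Wls (0.87), and replicate 4 was high for Igfbp5 (0.881).

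The change in the mutants differed between lines by a test of the difference itself. Between Leca4 and Leca2 it did for 329 genes, with the log2 difference at 2.90 for Cryab, 2.77 for Neurog1, 2.74 for Crabp1, 2.69 for Eya4 and 2.59 for Dbx1. In the other direction it was -2.70 for Dmrta1, -2.15 for Meis1, -2.06 for G630016G05Rik, -1.73 for Tnc and -1.70 for Ptx3. The value for Cryab includes groups at or below the level of the filter. By camera the microglial list differed by a median of 0.43 and the Notch list by 0.20. Neither was called with an estimated correlation (adjusted p = 0.725 and 0.935) or with fry (adjusted p = 0.0743 and 0.128), and 0 of 12 microglial genes differed singly. Without Leca2 control replicate 1 the number of genes was 201, and with a block of replicate numbers it was 148, with 128 of the 329 kept. Relabelling mutant and control arrays within both lines asks whether the labels matter at all, not whether 2 lines change alike. It therefore cannot exclude chance for the difference between lines. Of 100 such relabellings, 3 gave as many genes, the real one included, with 911 genes as the highest other. That relabelling kept Leca4 as it was and exchanged arrays in Leca2, where no other split of the 7 Leca2 arrays alone called more than 20 genes, and what raised its count was not tested.

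Between Sey and Leca4 the change differed for 1778 genes, with differences of 5.35 for Dlx6os1, 4.76 for Dlx1, 4.43 for Slc18a2, 4.27 for Dlx2 and 4.05 for Dlx5. In the other direction they were -4.94 for Rlbp1, -4.01 for Neurog1, -2.97 for Fbln7, -2.84 for Cryab and -2.60 for Ccn2. The values for Slc18a2, Rlbp1, Fbln7 and Cryab include a group at or below the level of the filter. Of 100 relabellings 2 gave as many genes, the real one included, and the highest other, which kept Sey as it was, gave 1945. For the reason given above, they cannot exclude chance. With the block 1015 genes were called.

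Between Sey and Leca2 it differed for 927 genes, with 4.16 for Dlx6os1, 3.69 for Uncx, 3.50 for Dlx5, 3.47 for Dlx1 and 3.27 for Sp8. In the other direction the differences were -4.22 for Dmrta1, -2.93 for Rlbp1, -2.66 for Lratd1, -2.62 for 9130024F11Rik and -2.50 for Gcg. Those of Uncx, Dmrta1 and Rlbp1 include such a group. For the same reason the relabellings cannot exclude chance here. Of 100, 3 gave as many genes, the real one included, with 1491 as the highest other. In that relabelling the 4 males of the Sey line stood against its 3 females, which also set its 3 controls and 1 mutant against the other mutants. With a term for sex the number of genes was 293, and with the block it was 559. Without Leca2 control replicate 1 the number of genes was 529 and without Sey control replicate 1 it was 582.

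Probe sets that name no gene were outside the gene results, and 3684 of them passed the filter. In Sey 244 of these were called, 134 up and 110 down. In Leca4 74 were called, 42 up and 32 down, and in Leca2 5 were, 2 up and 3 down.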

How the results depend on the processing

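The sex term, the removal of genes near Pax6 and on the sex chromosomes, and the list tests on rescaled values were chosen after the data were seen. Where no cause is named, the cause was not tested. With 1 array left out the number of genes changed ranged from 2106 to 2563 in Sey, 512 to 749 in Leca4 (512 without Leca4 mutant replicate 1) and 40 to 61 in Leca2 (40 without Leca2 mutant replicate 2). For the differences it ranged from 201 to 398 between Leca4 and Leca2, 1326 to 1871 between Sey and Leca4 and 529 to 1072 between Sey and Leca2. It ranged from 5413 to 6240 between the Leca4 and Leca2 controls and from 9353 to 10001 between Sey and 129 S6 controls. Shared changes in the same direction ranged from 116 to 216 for Sey and Leca4, 32 to 49 for Sey and Leca2 and 13 to 21 for Leca4 and Leca2. The number of lists called ranged from 10 to 12 in Sey, 1 to 5 in Leca4, 2 to 7 in Leca2 and 2 to 5 for the Leca4 and Leca2 difference. The extremes came without Leca4 control replicate 3 (1) and Leca4 mutant replicate 2 (5) in Leca4 and without Leca2 mutant replicate 3 (2) in Leca2. For the difference, 4 lists were called without Leca2 mutant replicate 3, Leca2 control replicate 1 or Leca2 control replicate 2, and 5 without Leca2 mutant replicate 4 or Leca4 mutant replicate 2.

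A fit of only the groups compared estimates the spread from their arrays alone. It called 400 genes in Leca4 and 27 in Leca2, and left shared changes of 113 for Sey and Leca4, 22 for Sey and Leca2 and 8 for Leca4 and Leca2. A block of replicate numbers called 450 genes in Leca4 and 28 in Leca2. With that block the differences held 148 genes between Leca4 and Leca2, 1015 between Sey and Leca4 and 559 between Sey and Leca2, the shared changes were 108, 24 and 7, and 5 lists differed between Leca4 and Leca2. The block also left the excess near Pax6 in Leca2 at an odds ratio of 5.47 (Fisher's exact p = 0.0581). The block also gained calls, those of Gria2 in Leca4 (adjusted p = 6.43e-04), of the ventral telencephalon list in Leca2 and of 3 lists for the Leca4 and Leca2 difference. Arrays with the same number in mutant and control correlated, after group means were removed, from -0.44 to 0.34.

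With every probe set tested on its own, which counts probe sets and not genes, 4311 were called in Sey, 110 in Leca2, 2672 for Sey against Leca4, 12495 between the Leca4 and Leca2 controls and 20498 between Sey and 129 S6 controls, and 68 were shared by Sey and Leca2. Array weights called 121 genes in Leca2 and 499 for Leca4 against Leca2, with 83 shared by Sey and Leca2 and 34 by Leca4 and Leca2. The looser adjusted p under 0.10 gave 611 genes for Leca4 against Leca2 and 1411 for Sey against Leca2, with 295 shared by Sey and Leca4 and 28 by Leca4 and Leca2. The stricter demand of a 1.4-fold change left 1057 in Sey, 330 in Leca4, 1043 for Sey against Leca4, 1194 and 4306 between the control groups and 92 shared by Sey and Leca4. Against all 129 S6 controls, which brings in the separate normalization of the lines, 2450 genes were called in Leca4 and 4050 in Leca2, and Cdh5 in Leca2 turned to -0.22. The Leca4 and Leca2 controls differed in 4120 genes after quantile normalization and 4052 after centring on the median. The mean of probe sets turned Aqr in Leca2 to -0.04 and Pdxdc1 between Sey and 129 S6 controls to 0.08. The sex term left 293 genes for Sey against Leca2, and in the other comparisons 1936 in Sey, 748 in Leca4 and 53 in Leca2. Without genes near Pax6 and on the sex chromosomes 2647 genes were called in Sey, 725 in Leca4 and 57 in Leca2.

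With an estimated correlation 0 lists were called in Sey, 0 in Leca4, 0 in Leca2 and 0 for the Leca4 and Leca2 difference. The fry test, which does not compare a list with other genes, called 1 in Leca2 and 0 for that difference. A window of 200 genes on each side of Pax6 raised the Sey odds ratio to 1.5 (Fisher's exact p = 6.23e-04). Of the single gene results, none turned direction under the other alternatives run. The number that lost their call was 31 with the 1.4-fold demand, 26 in the fit of only the groups compared, 30 with the block and 10 with the sex term. With the mean of probe sets it was 10, not counting Aqr and Pdxdc1, which turned direction. The filter kept genes with 3 arrays above its level, so a gene can lie at or below it in a whole group, where the fold is only a bound. Of the genes called, 1 group alone did so for 30 (mutants) and 26 (controls) in Sey, 13 and 18 in Leca4 and 3 and 1 in Leca2, and both groups did for 17, 2 and 1.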

Other observations

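Of the tests in this part, the correlation of changes near Pax6 between the Leca lines and the model with a sex term were chosen only after the result was seen. Sey and Leca4 changed 91 genes in opposite directions. Independent lists of these sizes would share 77.4, so the count alone shows little excess. Among the 91 were regulators of neural development, named here after their values were seen. The homeobox gene Pbx3 changed by 2.32 ± 0.34 in Sey and -1.38 ± 0.34 in Leca4, though its call in Leca4 was lost without Leca4 mutant replicate 1 or 3 or Leca4 control replicate 3 (highest adjusted p = 0.107). The forkhead gene Foxp2 changed by 0.83 ± 0.13 and -0.60 ± 0.13, and Neurog1 by -2.67 ± 0.15 and 1.34 ± 0.15. In Leca2 the same genes stood at 0.05 ± 0.34, -0.16 ± 0.13 and -1.43 ± 0.15, and of these Neurog1 was called.

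Calls were spread unevenly over the chromosomes in each mutant. Chromosome 2, which carries Pax6, held 272 calls among 1113 genes in Sey (24.4%, against 19.9% elsewhere; Fisher's exact test, adjusted p = 0.00341). It held 100 in Leca4 (8.98%, against 5.34%; adjusted p = 4.94e-05, exact) and 15 in Leca2 (1.35%, against 0.395%; adjusted p = 0.0033, exact). Chromosome 17 held fewer calls than the others in Sey (91 of 675, 13.5% against 20.6%; adjusted p = 7.2e-05, exact) and in Leca4 (19 of 675, 2.81% against 5.78%; adjusted p = 0.00574, exact), and chromosome 11 did in Sey (186 of 1132, 16.4% against 20.6%; adjusted p = 0.00515, exact).

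The number of genes changed was weighed against chance and, in Sey, against the uneven sex of the embryos. In each of the 3 mutants 1 of the 35 splits of the line's 7 arrays, the real one, gave as many genes. That is the smallest share that 35 splits allow, so it argues against chance in each line but cannot exclude it. Sey had 2791 genes against a highest other of 1186 (the split of the 4 males, 3 controls and 1 mutant, from the 3 females). Leca4 had 779 against 198 and Leca2 66 against 20. With a sex term 1936 genes were called in Sey and 1872 of the 2791 remained called, and 99 of 441 genes on the sex chromosomes were called (odds ratio 1.15, Fisher's exact p = 0.228), which argues against sex as the whole cause. That the count follows the Pax6 genotype is a hypothesis that these tests leave standing, beside others not weighed here. Sex may account for part of the calls that the term removed. Litter was not tested, since the labels do not give it.

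The calls near Pax6 could come from chromosome 2 sequence that was carried along with each mutant allele, or from a response to the loss of Pax6 function. In Leca4 the genes near Pax6 followed Sey in 4.17% of calls (1 of 24), against 24.8% elsewhere (186 of 751; Fisher's exact p = 0.0152), which argues against a response shared with Sey. In Leca2, with Paupar left out by a rule set beforehand, it was 40% (2 of 5) against 70.7% (41 of 58; Fisher's exact p = 0.315), too few genes to tell. Paupar itself rose in both Leca2 (1.48) and Sey (1.90). For a haplotype common to both Leca lines, the changes of the 200 genes correlated with r of 0.13 across genes, against a median of -0.05 in 58 windows elsewhere (from -0.41 to 0.35), which lies within their range, at percentile 89.7. Of the genes called near Pax6, 2 were called in both Leca lines, in the same direction. They were Aqr (0.42 in Leca4 and 0.37 in Leca2) and, named after its values were seen, Eif2ak4 (-0.22 and -0.30). Aqr stayed called in each line without any 1 of its arrays (highest adjusted p = 0.00341 and 0.0408). In Leca2, though, it was not called in a fit of only the 7 arrays of the line (adjusted p = 0.0718) or with a block of replicate numbers (adjusted p = 0.113), and its other 2 probe sets had the opposite sign, so that the mean of all 3 changed by -0.04. Eif2ak4 lost its call in 6 of the 7 such fits in each line, all but those without Leca4 control replicate 4 and without Leca2 mutant replicate 4 (highest adjusted p = 0.158 and 0.193). These values leave the explanation open. A haplotype particular to each line and altered hybridization to strain variants were not tested.

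Meninges in the dissected tissue might bring transcripts such as those of Ccn2, Col6a3, Npnt and Fbln7, 4 of the largest rises in Leca4, put together after their values were seen and not a list fixed beforehand. The 11 tested genes of the meninges and mesenchyme list had a median of 0.04 (SE of the median 0.13; camera adjusted p = 0.825), and 2 exceeded 0.5. The 2 that exceeded 0.5 were Crabp2 (1.17) and Prrx1 (0.95), which were called. Other members, not chosen by a rule, stood at -0.42 ± 0.15 (Col1a2), -0.23 ± 0.13 (Col3a1), -0.32 ± 0.25 (Dcn), 0.04 ± 0.07 (Bgn) and -0.23 ± 0.08 (Igf2). None of these was called with all arrays (Igf2 was without Leca4 control replicate 2, adjusted p = 0.0213). The list as a whole argues against meninges as the source of the 4 rises. The cause of these rises stays open.

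The control groups differed beyond other splits of the same arrays. Between the Leca4 and Leca2 controls 6561 genes differed, against a highest other of 3529 over 35 splits, and between Sey and 129 S6 controls 10067, against 5754 over 100 splits, with 1 split as large in each, the real one. The arrays appear to have been normalized per line, so a split that mixes lines has a wider spread within its groups. That alone can make the real split the largest, and these counts cannot say whether the controls differ beyond the processing. The line and its normalization are confounded in both differences, and strain as well between Sey and the Leca controls. Sex was uneven too, with 3 of 3 males among the Sey controls, 3 of 4 in Leca4 and 0 of 3 in Leca2.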
